A study of Homo sapiens with 8 samples.

How the data were processed

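Total RNA of FHC and HCT116 cells was converted to cRNA, labelled with Cy3 and hybridised to Agilent arrays of mRNA, lncRNA and circRNA probes, per the labels' protocols. The scanner output was made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. It holds spot intensity as processed signal, mean signal and local background, with no normalization between arrays, per the file headers. The authors also deposited a table of the whole series with a log2 normalized value per probe. How those log2 values were made is not given in the sources used here, and all 8 columns share the same quantiles, as quantile normalization gives. Its raw columns matched the scanner files, with at least 99.97% of probes within 1%. The per-spot flags are deposited by the authors as 0 or 1.

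The main analysis started from the scanner files. Each array had 175906 spots outside the controls, and 85470 to 103450 of them were well above background. No spot was saturated. Control spots and spots flagged as outliers were left out, spots of one probe were averaged as log2, and each array's 75th percentile was subtracted. Probes had to be well above background on all arrays of at least 1 line. Of several probes of a gene, the one with the highest mean over the 8 arrays was kept, so other probes of the gene can differ. A probe well above background on no array of a line has only a bound there. Its fold is then given as at least the bright line's mean over the dim line's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Groups were compared as HCT116 minus FHC with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment within each RNA class, and values are means ± SD over 4 arrays of log2 signal minus the 75th percentile.

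Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 against all other mRNAs, adjusted over 22 lists. The named transcripts were the 8 mRNAs, 4 lncRNAs and 4 circRNAs with the largest rise and as many with the largest fall among calls whose arrays did not overlap between lines. For lncRNAs, symbols that are not bare clone or accession names came first; what counts as such a name was settled after lncRNA values had been seen. The 3 members of each list with the smallest p were added. Some results that the rule takes in are not reported here, and genes of the X inactivation centre and the Y chromosome were not named. Of 20488 mRNA symbols in the files, 18876 were current and 1217 were updated through the reference gene table. Of the list members, 1 cancer-testis gene, 4 lncRNAs and 10 of 13 known circRNAs had no matching probe. Members counted as measured are those with a probe that passed the filter on signal above background. Among members with a probe, 17 of 24 cancer-testis, 12 of 39 HOX, 7 of 20 mesenchymal and 5 of 28 intestinal genes did not pass it, nor did many markers of other cell types. Coordinates are those of the deposited table, which names no build. For 98.3% of mRNA probes from GENCODE they lay at the gene's place in GRCh38, and for 17% of circRNA probes from circBase, so none is given for circRNAs.

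On data simulated from 14294 mRNAs, 98.5% of log2 changes of 2 were called with the spread of FHC and 73.1% with the pooled spread of both lines. For 35279 lncRNAs the shares were 92.5% and 34.3%, and for 36674 circRNAs 95.5% and 50.8%. Each share rests on 67 changed transcripts, with independent noise of equal spread in both lines. In the data the spread was wider in HCT116 and transcripts shifted together by array, so the shares may not hold there. Alternatives were normexp background correction (offset 50), quantile normalization, scaling to detected probes or to the 10 spike-in probes, no filter and a stricter filter, the mean of a gene's probes, eBayes with trend and robust settings, a replicate block, the deposited table, other fold thresholds, an estimated correlation, and leaving out each array. Chosen after the data were seen were HCT116 replicate 4 alone against FHC, cyclic loess and the percentile over detected probes. A probe counted as well above background on an array where at least 0.5 of its spots were. Bright probes, used for comparing the HCT116 arrays, had a mean log2 signal over 8, or over 10 in FHC where FHC was the reference. These cutoffs were set after the arrays' brightness had been seen. In each setting but the mean of probes, the brightest probe of a gene was chosen again. With HCT116 replicate 4 alone 217 of 14297 mRNAs and 48 of 35294 lncRNAs were read from another probe than with all 8 arrays, the most of any setting. A slide block was not run, because each slide held 1 line.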

Results

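RNA from 2 human cell lines was profiled on 8 one-colour arrays carrying probes for mRNAs, long noncoding RNAs and circular RNAs. HCT116 is a colorectal carcinoma line and FHC is labelled as normal colorectal epithelium. Each line had 4 arrays, numbered 1 to 4 in the labels. Nothing in the labels says that these came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. All 4 FHC arrays lay on one slide and all 4 HCT116 arrays on the other, so slide and cell line cannot be told apart. Of 26345 mRNA, 100831 lncRNA and 47899 circRNA probes, 14297 mRNAs, 35294 lncRNAs and 36682 circRNAs were well above background on every array of at least 1 line and were tested. The number of arrays limits the precision.

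The HCT116 arrays were not alike. The 75th percentile of signal was 47.4, 33.8 and 35.5 intensity units on HCT116 replicates 1, 2 and 3, 106 on HCT116 replicate 4, and 84.1 to 105 on the FHC arrays. Median circRNA signal was 29.8, 20.4, 21.4 and 73 on HCT116 replicates 1 to 4. The 3' to 5' signal ratio of the GAPDH control probes was 5.65, 7.43, 6.86 and 4.96 on these arrays, against 4.25 to 4.55 on FHC. Across mRNAs, which are not independent replicates, HCT116 replicate 4 correlated with HCT116 replicates 1, 2 and 3 at r = 0.908, 0.842 and 0.838, and with the FHC arrays at 0.867 to 0.871. The median standard deviation of an mRNA was 0.14 log2 units within FHC and 0.69 within HCT116. Each gene group below is therefore also given with HCT116 replicate 4 as the only HCT116 array, a setting chosen after the data were seen, in which the lone array is assumed to vary like FHC.

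**Figure D1:**
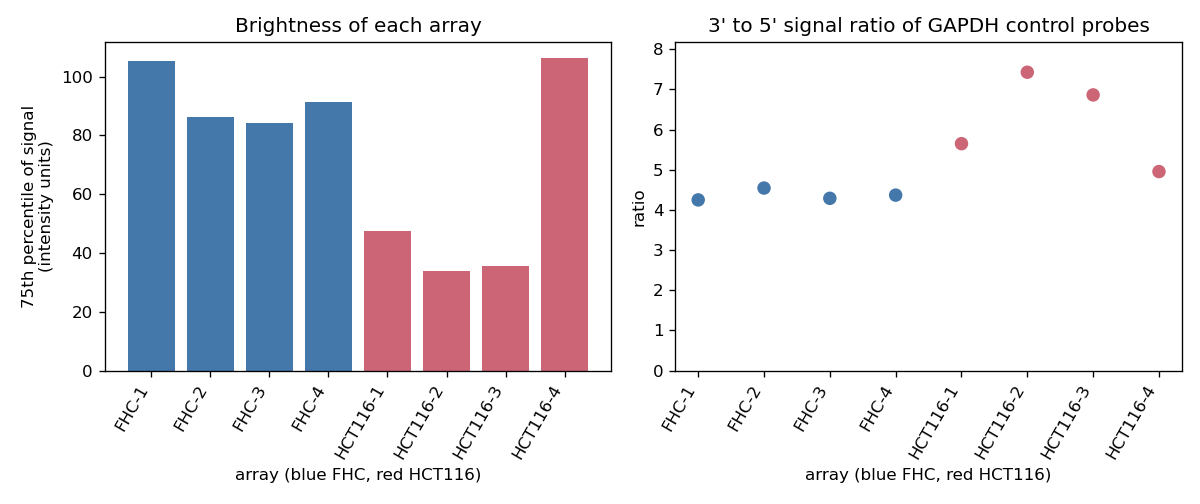
Left, bars give the 75th percentile of processed signal (intensity units) of each array, with FHC in blue and HCT116 in red; right, points give the ratio of 3' to 5' signal of the GAPDH control probes. HCT116 replicates 1 to 3 lie at 33.8 to 47.4 intensity units and replicate 4 at 106.

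The mRNA comparison asked which protein-coding transcripts differ between the carcinoma line and the normal line. The largest rises in HCT116 were in EEF1A2, a translation elongation factor, in the metallothioneins MT1M and MT1E, in the neuropeptide gene GAL, and in CDX1, an intestinal homeobox transcription factor. Among the largest falls were those in the cystatins CST1, CST2 and CST4, in LYZ, which encodes lysozyme, and in PMCH, the precursor of melanin-concentrating hormone. Levels are log2 signals relative to the array's 75th percentile, as mean ± SD over the 4 arrays of a line. Normalized MT1E was -1.45 ± 0.16 in FHC and 10.36 ± 0.90 in HCT116 (log2 fold change 11.81, standard error 0.41, adjusted p = 1.05e-07). CDX1 (chromosome 5, 150166795 to 150184558) was not well above background on any FHC array and was at least 2644-fold higher in HCT116 (adjusted p = 1.48e-08). GAL was at least 895-fold higher, the histone gene H2AC25 at least 314-fold and the phosphatase gene DUSP23 at least 825-fold. EEF1A2, MT1M and NKD2, which encodes a Dishevelled-binding Wnt antagonist, had log2 fold changes of 12.76, 12.72 and 9.90, and were well above background on 2, 1 and 1 of 4 FHC arrays. LYZ (chromosome 12, 69348341 to 69354234) was 8.92 ± 0.053 in FHC and -1.90 ± 0.39 in HCT116 (log2 fold change -10.82, standard error 0.26, adjusted p = 1.48e-08). PMCH was at least 357-fold lower in HCT116, CST4 at least 212-fold and CST2 at least 176-fold. GALC, which encodes galactosylceramidase, has 2 probes that disagree: the one used was well above background on no HCT116 array and the other on all 4. With probes detected on all arrays only, which keeps the other probe, its log2 fold change was -0.33 (adjusted p = 0.537), so a fall of GALC is not settled. CST1 and DKK1, a secreted Wnt inhibitor, had log2 fold changes of -11.63 and -8.79. LYZ was well above background on 2, CST1 on 1 and DKK1 on 2 of 4 HCT116 arrays. The cystatin probes and the metallothionein probes target close paralogs, so the share of each gene in these signals is uncertain.

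In all, 6073 mRNAs passed the limma test (Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1), 2527 higher and 3546 lower in HCT116. The 4 values of one line lay wholly outside those of the other for 6369 mRNAs, 44.6%. For 1 mRNA taken alone, with interchangeable arrays, chance gives 2.86%. Shifts of whole arrays move many mRNAs together, so that share does not measure chance across mRNAs. With HCT116 replicate 4 as the only HCT116 array, 4328 mRNAs were called, 2410 of them also called in the same direction with all 8 arrays. When that array was left out, 9152 were called. The balance of directions depended on the scaling and on the arrays used. With HCT116 replicate 4 as the only HCT116 array, rises outnumbered falls among the calls. With all 8 arrays the share of calls lower in HCT116 was 58.4%. It was 78.5% with normexp, 92.3% with spike-in scaling, 30.2% with the percentile taken over probes detected on all arrays and 42.6% with cyclic loess. The median log2 fold change of all mRNAs tested was -0.25, against -1.50 with spike-in scaling and 0.36 with the percentile over probes detected on all arrays.

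**Figure D2:**
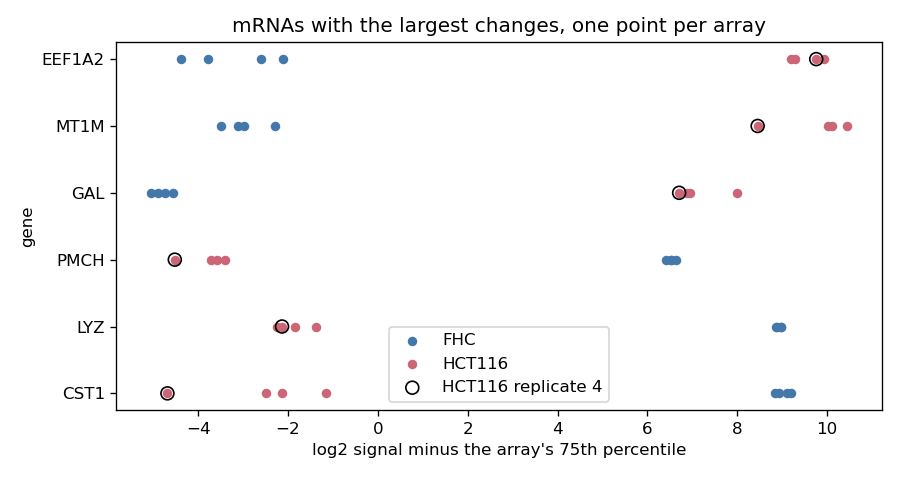
Each point is 1 array's log2 signal minus that array's 75th percentile (horizontal axis) for the 3 mRNAs with the largest rises and the 3 with the largest falls (vertical axis), with FHC in blue, HCT116 in red and HCT116 replicate 4 circled. For every gene drawn, the 4 arrays of one line lie apart from the 4 of the other.

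Most measured genes of intestinal epithelial identity and most measured HOX genes rose in HCT116. With spike-in scaling, however, the counts were 5 higher and 2 lower for the intestinal genes and 4 higher and 4 lower for HOX genes. For each list, the settings are given that moved the count of its leading direction, or of either direction where the smaller was at least 2/3 of the larger, by over 1.5 times or turned its balance, among the scalings tried and the arrays left out in turn, and every setting that changed whether the list passed. Lists were compared with all other mRNAs, and medians are given relative to the median of all mRNAs. None of the 11 lists that passed at the preset correlation passed with an estimated one. Of the 35 ways to split the 8 arrays into 4 and 4, 5 put as many lists past the threshold, the split by line included. The other 4 keep part of the difference between the lines, so they do not measure chance. Of the intestinal list, 14 members rose, 2 fell and 7 did not pass, of 23 measured (adjusted over the list alone, 15 rose and 2 fell). TFF3, a secreted mucosal repair peptide, was 0.0092 ± 0.23 in FHC and 6.63 ± 0.21 in HCT116 (log2 fold change 6.62, standard error 0.24, adjusted p = 1.05e-07), and LGALS4, an epithelial lectin, had a log2 fold change of 4.02. The list stood at median 1.79 relative to all mRNAs, camera adjusted p = 7.51e-05, and adjusted p = 0.214 with an estimated correlation. The intestinal epithelial identity counts became 16 higher and 2 lower of 26 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 7.96e-05). Intestinal counts were 9 higher and 2 lower with normexp. Of the HOX genes, 17 members rose, 2 fell and 8 did not pass, of 27 measured (adjusted over the list alone, 19 rose and 2 fell). HOXB8 and HOXB4 had log2 fold changes of 4.70 and 6.78, and HOXA11 was at least 38.4-fold higher. The list stood at median 1.70 relative to all mRNAs, camera adjusted p = 7.51e-05, and adjusted p = 0.214 with an estimated correlation. When HCT116 replicate 4 was the only HCT116 array, 16 rose and 2 fell of 30 (camera adjusted p = 6.40e-04). HOX counts were 9 higher and 0 lower with normexp.

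Epithelial adhesion genes mostly fell. Of the list, 3 members rose, 16 fell and 9 did not pass, of 28 measured (adjusted over the list alone, 3 rose and 17 fell; median -0.93 relative to all mRNAs, camera adjusted p = 0.00413, and adjusted p = 0.571 with an estimated correlation). RAB25, a vesicle-traffic GTPase of epithelia, was 7.52 ± 0.13 in FHC and 3.18 ± 0.54 in HCT116 (log2 fold change -4.34, standard error 0.30, adjusted p = 5.37e-06). CLDN3, a tight-junction claudin, went the other way, with a log2 fold change of 7.41. Replicate 4 of HCT116, as the only HCT116 array, gave 3 higher and 12 lower of 28 (camera adjusted p = 0.0221). The epithelial list did not pass with spike-in scaling (adjusted p = 0.0628). Of mesenchymal genes, 5 members rose, 2 fell and 6 did not pass, of 13 measured (adjusted over the list alone, 5 rose and 2 fell), and the list did not pass (median 1.22 relative to all mRNAs, camera adjusted p = 0.137, and adjusted p = 0.442 with an estimated correlation). S100A4, a calcium-binding protein, had a log2 fold change of 4.01 and AKAP12, a kinase-anchoring protein, 1.79 (well above background on 2 of 4 FHC arrays), while MSN, which encodes moesin, was at least 20.2-fold lower. On HCT116 replicate 4 as the only HCT116 array, 5 of 14 rose and 2 fell (camera adjusted p = 0.629). Mesenchymal counts were 1 higher and 3 lower with normexp or with spike-in scaling, 8 higher and 2 lower with the percentile over probes detected on all arrays, and 3 higher and 2 lower with cyclic loess. They were 9 higher and 2 lower without HCT116 replicate 4. The mesenchymal list passed with probes detected on all arrays only (adjusted p = 0.0444). With normexp, with spike-in scaling or with cyclic loess, the call was lost for AKAP12.

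Cell cycle genes fell as a list. 1 member rose, 20 fell and 15 did not pass, of 36 measured (adjusted over the list alone, 1 rose and 20 fell; median -1.02 relative to all mRNAs, camera adjusted p = 2.49e-04, and adjusted p = 0.477 with an estimated correlation). AURKA, a mitotic kinase, was 8.43 ± 0.056 in FHC and 5.90 ± 0.91 in HCT116 (log2 fold change -2.53, standard error 0.41, adjusted p = 0.00138), and CCNE1, a G1/S cyclin, and PCNA, the replication clamp, had log2 fold changes of -2.02 and -2.43. The cell cycle counts became 0 higher and 19 lower of 36 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 6.06e-09). Cell cycle counts were 0 higher and 32 lower with spike-in scaling, 2 higher and 13 lower with the percentile over probes detected on all arrays, and 1 higher and 13 lower with cyclic loess. Of p53 targets, 2 members rose, 12 fell and 8 did not pass, of 22 measured (adjusted over the list alone, 2 rose and 13 fell; median -1.01 relative to all mRNAs, camera adjusted p = 0.00544, and adjusted p = 0.477 with an estimated correlation). MDM2 and TIGAR had log2 fold changes of -2.06 and -2.60, and TP53INP1 was at least 3.69-fold lower. When HCT116 replicate 4 was the only HCT116 array, 3 rose and 10 fell of 22 (camera adjusted p = 0.0629). The p53 target list did not pass with spike-in scaling (adjusted p = 0.0809). Of mismatch repair genes, 0 members rose, 6 fell and 5 did not pass, of 11 measured (adjusted over the list alone, 0 rose and 6 fell; median -1.09 relative to all mRNAs, camera adjusted p = 0.00844, and adjusted p = 0.477 with an estimated correlation). MSH6, which recognises mismatches, had a log2 fold change of -4.47 and LIG1, a DNA ligase, -1.56. MSH6 was well above background on 1 and LIG1 on 3 of 4 HCT116 arrays. PCNA, at -2.43, is a member of this list too, so its fall is not independent of that of the cell cycle list. Replicate 4 of HCT116, as the only HCT116 array, gave 1 higher and 4 lower of 11 (camera adjusted p = 0.238). Mismatch repair counts were 0 higher and 3 lower with the percentile over probes detected on all arrays. The mismatch repair list did not pass with spike-in scaling (adjusted p = 0.0628). With normexp, the call was lost for LIG1 and TP53INP1. With the percentile over probes detected on all arrays, no call was made for LIG1.

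Interferon-stimulated genes fell as a list. 2 members rose, 12 fell and 10 did not pass, of 24 measured (adjusted over the list alone, 2 rose and 13 fell; median -1.15 relative to all mRNAs, camera adjusted p = 0.0089, and adjusted p = 0.37 with an estimated correlation). MX2, an interferon-induced GTPase, was 3.38 ± 0.13 in FHC and -0.44 ± 0.44 in HCT116 (log2 fold change -3.82, standard error 0.27, adjusted p = 6.96e-06), and IFI27 had a log2 fold change of -2.88. On HCT116 replicate 4 as the only HCT116 array, 4 of 24 rose and 11 fell (camera adjusted p = 0.00531). Of HLA class I and antigen processing genes, 0 members rose, 5 fell and 10 did not pass, of 15 measured (adjusted over the list alone, 0 rose and 4 fell), and the list did not pass (median 0.40 relative to all mRNAs, camera adjusted p = 0.899, and adjusted p = 1 with an estimated correlation). Its median was 0.15 and its mean -0.37, which differ in sign. B2M, the class I light chain, had a log2 fold change of -2.48, CALR -1.57 and PDIA3 -2.16. The HLA class I and antigen processing counts became 2 higher and 2 lower of 15 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 0.989). HLA counts were 4 higher and 2 lower with the percentile over probes detected on all arrays. They were 0 higher and 3 lower without FHC replicate 1, 2, 3 or 4 or without HCT116 replicate 3, and 1 higher and 3 lower without HCT116 replicate 2. Of secreted cytokines and proteases, 10 members rose, 6 fell and 6 did not pass, of 22 measured (adjusted over the list alone, 10 rose and 6 fell), without passing as a list (median 0.60 relative to all mRNAs, camera adjusted p = 0.252, and adjusted p = 0.477 with an estimated correlation). The collagenase MMP1 had a log2 fold change of -5.31 (well above background on 3 of 4 HCT116 arrays), the chemokine CCL5 3.79 and IGFBP4 2.89. When HCT116 replicate 4 was the only HCT116 array, 6 rose and 5 fell of 22 (camera adjusted p = 0.989). Cytokine counts were 3 higher and 5 lower with normexp, and 2 higher and 7 lower with spike-in scaling. The cytokine list passed with probes detected on all arrays only (adjusted p = 0.0444). The cytokine median of 0.35 and mean of -0.023 differed in sign. With spike-in scaling, the call was lost for IGFBP4. With the percentile over probes detected on all arrays, no call was made for CALR. With only replicate 4 for HCT116, the call was lost for PDIA3.

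Wnt, MAPK and TGF-beta lists did not pass with all 8 arrays. Of Wnt genes, 3 members rose, 8 fell and 7 did not pass, of 18 measured (adjusted over the list alone, 3 rose and 8 fell; median -0.98 relative to all mRNAs, camera adjusted p = 0.214, and adjusted p = 0.742 with an estimated correlation). LGR5, a stem cell receptor, was 3.95 ± 0.097 in FHC and -0.84 ± 0.68 in HCT116 (log2 fold change -4.78, standard error 0.34, adjusted p = 6.36e-06), and the transcription factor gene SP5 had a log2 fold change of -4.95. Replicate 4 of HCT116, as the only HCT116 array, gave 3 higher and 4 lower of 19 (camera adjusted p = 0.84). Of MAPK output genes, 4 members rose, 4 fell and 9 did not pass, of 17 measured (adjusted over the list alone, 4 rose and 4 fell; median -0.097 relative to all mRNAs, camera adjusted p = 0.999, and adjusted p = 1 with an estimated correlation). The phosphatase gene DUSP4 and the receptor gene EPHA4 had log2 fold changes of -2.73 and -3.26, with EPHA4 well above background on 1 of 4 HCT116 arrays. AREG, which encodes the growth factor amphiregulin, was -3.33 ± 0.92 in FHC and 3.87 ± 2.84 in HCT116 (log2 fold change 7.20, standard error 1.19, adjusted p = 0.00151) and was well above background on 1 of 4 FHC arrays. On HCT116 replicate 4 as the only HCT116 array, 11 of 19 rose and 2 fell (camera adjusted p = 7.76e-04), so this list passed on that array and pointed the other way from all 8. MAPK counts were 1 higher and 3 lower with normexp or with spike-in scaling. They were 4 higher and 2 lower without FHC replicate 1, 2, 3 or 4 or without HCT116 replicate 1, 2 or 3, and 4 higher and 7 lower without HCT116 replicate 4. Of TGF-beta targets, 3 members rose, 2 fell and 9 did not pass, of 14 measured (adjusted over the list alone, 3 rose and 3 fell; median -0.26 relative to all mRNAs, camera adjusted p = 0.999, and adjusted p = 1 with an estimated correlation). TGFB1I1 was at least 13.4-fold higher, and TAGLN and JUNB had log2 fold changes of -4.81 and 1.11, with TAGLN well above background on 3 of 4 HCT116 arrays and the sign of JUNB turned by spike-in scaling. The TGF-beta targets counts became 6 higher and 1 lower of 15 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 0.0825). TGF-beta counts were 1 higher and 3 lower with normexp, 1 higher and 4 lower with spike-in scaling, and 5 higher and 2 lower with the percentile over probes detected on all arrays. They were 3 higher and 6 lower without HCT116 replicate 4. The TGF-beta median of -0.52 had the sign opposite to the camera direction. With normexp, with spike-in scaling, with only replicate 4 for HCT116 or without HCT116 replicate 3, the call was lost for JUNB.

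Markers of other cell types were measured because a sample could hold other cells. Of these, 12 of 24 fibroblast, 9 of 14 endothelial, 8 of 17 leukocyte and 4 of 14 smooth muscle genes did not pass the filter. They were not well above background on all arrays of either line, and the counts below leave them out. Of fibroblast matrix genes, 5 members rose, 0 fell and 7 did not pass, of 12 measured (adjusted over the list alone, 5 rose and 0 fell; median 1.1 relative to all mRNAs, camera adjusted p = 0.0215, and adjusted p = 0.37 with an estimated correlation), with SPARC at a log2 fold change of 2.78, BGN at 1.13 and THY1 at 1.59. When HCT116 replicate 4 was the only HCT116 array, 4 rose and 2 fell of 12 (camera adjusted p = 0.84). Fibroblast counts were 1 higher and 0 lower with normexp, 3 higher and 0 lower with quantile normalization or with the deposited table, 0 higher and 1 lower with spike-in scaling, and 2 higher and 0 lower with cyclic loess. They were 2 higher and 0 lower without FHC replicate 1 or 4 or without HCT116 replicate 2 or 3, 1 higher and 0 lower without FHC replicate 2, 3 higher and 0 lower without HCT116 replicate 1, and 8 higher and 0 lower without HCT116 replicate 4. The fibroblast list did not pass with quantile normalization (adjusted p = 0.0838), with spike-in scaling (adjusted p = 0.0953), with probes detected on all arrays only (adjusted p = 0.125), with the deposited table (adjusted p = 0.084) or with cyclic loess (adjusted p = 0.279). Of endothelial genes, 3 members rose, 0 fell and 2 did not pass, of 5 measured (adjusted over the list alone, 3 rose and 0 fell; median 1.38 relative to all mRNAs, camera adjusted p = 0.00413, and adjusted p = 0.214 with an estimated correlation), with EGFL7 at 4.91, CLEC14A at 3.80 and TIE1 at 1.13. Replicate 4 of HCT116, as the only HCT116 array, gave 4 higher and 0 lower of 5 (camera adjusted p = 0.0745). Endothelial counts were 5 higher and 0 lower without HCT116 replicate 4. The endothelial list did not pass with cyclic loess (adjusted p = 0.0651). Of leukocyte genes, 5 members rose, 0 fell and 4 did not pass, of 9 measured (adjusted over the list alone, 6 rose and 0 fell; median 1.42 relative to all mRNAs, camera adjusted p = 0.00413, and adjusted p = 0.487 with an estimated correlation), with CORO1A at 2.80, LAPTM5 at 1.90 and CD2 at 1.13. On HCT116 replicate 4 as the only HCT116 array, 2 of 10 rose and 1 fell (camera adjusted p = 0.714). Leukocyte counts were 1 higher and 0 lower with normexp or with spike-in scaling, and 3 higher and 0 lower with cyclic loess. They were 9 higher and 0 lower without HCT116 replicate 4. The leukocyte list did not pass with cyclic loess (adjusted p = 0.0651). Of smooth muscle genes, 3 members rose, 1 fell and 6 did not pass, of 10 measured (adjusted over the list alone, 3 rose and 1 fell; median -0.28 relative to all mRNAs, camera adjusted p = 0.836, and adjusted p = 0.888 with an estimated correlation), with TPM2 at 8.72 and DES at 2.27. The 1 that fell was TAGLN, at -4.81. SPARC was well above background on 3 and DES on 1 of 4 FHC arrays, and the TPM2 probe used on 3, while over both its probes TPM2 was so on all 4 and the mean of these gave 4.88. TIE1 was well above background on 3 of 4 HCT116 arrays. The smooth muscle and myofibroblast counts became 0 higher and 1 lower of 10 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 0.714). In that setting TPM2 was read from its other probe, at 0.39 and not called, while the probe used with all 8 arrays differed by 8.73 there, so the absence of rises includes this switch of probe. Smooth muscle counts were 1 higher and 4 lower with spike-in scaling. The smooth muscle median of -0.54 and mean of 0.60 differed in sign. The signs of TIE1, BGN and CD2 flipped with spike-in scaling. Their FHC means were -2.32, -1.24 and -1.85, and the dimmest probes well above background there lay at -2.92 to -2.50. The percentile subtracted was 5.07 to 5.56 log2 units on HCT116 replicates 1 to 3, 6.72 on replicate 4 and 6.38 to 6.71 on FHC. Subtracting less raises values on the dim arrays, so these small rises cannot be told apart from an effect of the scaling. With normexp, the call was lost for DES, TIE1, LAPTM5, CD2, BGN and THY1. With quantile normalization or with the deposited table, no call was made for TIE1 and CD2. With spike-in scaling, the call was lost for DES, TIE1, LAPTM5, CD2, SPARC, BGN and THY1. With cyclic loess, no call was made for TIE1, CD2 and BGN. With only replicate 4 for HCT116, the call was lost for DES, CD2, BGN and THY1. Without FHC replicate 1, no call was made for TIE1 and THY1. Without FHC replicate 2 or without HCT116 replicate 2, the call was lost for BGN and THY1. Without FHC replicate 4, without HCT116 replicate 1 or without HCT116 replicate 3, no call was made for THY1.

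Factors of circRNA biogenesis and turnover fell as a list with all 8 arrays. 0 members rose, 13 fell and 13 did not pass, of 26 measured (adjusted over the list alone, 0 rose and 13 fell; median -1.05 relative to all mRNAs, camera adjusted p = 0.00154, and adjusted p = 0.58 with an estimated correlation). ESRP1, an epithelial splicing regulator, was 2.55 ± 0.097 in FHC and 0.039 ± 0.22 in HCT116 (log2 fold change -2.51, standard error 0.22, adjusted p = 2.97e-05), and DHX9, a helicase, and SRSF3, a splicing factor, had log2 fold changes of -2.64 and -2.43, with SRSF3 well above background on 1 of 4 HCT116 arrays. When HCT116 replicate 4 was the only HCT116 array, 3 rose and 7 fell of 26 (camera adjusted p = 0.419). CircRNA factor counts were 0 higher and 7 lower with the percentile over probes detected on all arrays, and 0 higher and 6 lower with cyclic loess. They were 0 higher and 21 lower without HCT116 replicate 4. Of housekeeping genes, 0 members rose, 5 fell and 16 did not pass, of 21 measured (adjusted over the list alone, 0 rose and 5 fell; median -0.52 relative to all mRNAs, camera adjusted p = 0.131, and adjusted p = 0.745 with an estimated correlation), with VCP at a log2 fold change of -1.49 and TBP at -1.27. Replicate 4 of HCT116, as the only HCT116 array, gave 0 higher and 2 lower of 21 (camera adjusted p = 0.317). Housekeeping counts were 1 higher and 2 lower with quantile normalization, with the deposited table or with the percentile over probes detected on all arrays, 0 higher and 9 lower with spike-in scaling, and 1 higher and 1 lower with cyclic loess. They were 0 higher and 3 lower without FHC replicate 1, 2 or 4 or without HCT116 replicate 2 or 3, and 1 higher and 10 lower without HCT116 replicate 4. The housekeeping list passed with normexp (adjusted p = 0.0359), with no filter (adjusted p = 0.00719) and with the mean of a gene's probes (adjusted p = 0.0235). Of glycolysis genes, 4 members rose, 2 fell and 14 did not pass, of 20 measured (adjusted over the list alone, 4 rose and 2 fell; median -0.041 relative to all mRNAs, camera adjusted p = 0.836, and adjusted p = 1 with an estimated correlation), led by the enolase gene ENO2 at 7.31, with SLC16A3 at 1.80 and HK1 at 1.53. On HCT116 replicate 4 as the only HCT116 array, 2 of 20 rose and 2 fell (camera adjusted p = 0.622). Glycolysis counts were 2 higher and 3 lower with normexp, and 1 higher and 8 lower with spike-in scaling. The glycolysis median of -0.29 and mean of 0.28 differed in sign. Of oxidative phosphorylation genes, 0 members rose, 3 fell and 27 did not pass, of 30 measured (adjusted over the list alone, 0 rose and 1 fell; median 0.087 relative to all mRNAs, camera adjusted p = 0.846, and adjusted p = 1 with an estimated correlation), with SDHC at -1.30 and COX7C, well above background on 1 of 4 HCT116 arrays, at -1.91. The oxidative phosphorylation counts became 0 higher and 2 lower of 30 with HCT116 replicate 4 as the only HCT116 array (camera adjusted p = 0.0825). Oxidative phosphorylation counts were 0 higher and 8 lower with spike-in scaling, and 5 higher and 1 lower with the percentile over probes detected on all arrays. They were 2 higher and 5 lower without HCT116 replicate 4. Of cancer-testis antigens, 4 members rose, 0 fell and 3 did not pass, of 7 measured (adjusted over the list alone, 4 rose and 0 fell; median 1.31 relative to all mRNAs, camera adjusted p = 0.0575, and adjusted p = 0.487 with an estimated correlation), with MAGEA2 at 1.36 and XAGE1B at 1.36. When HCT116 replicate 4 was the only HCT116 array, 0 rose and 0 fell of 8 (camera adjusted p = 0.419). Cancer-testis counts were 0 higher and 0 lower with normexp or with spike-in scaling. They were 1 higher and 0 lower without FHC replicate 1 or 2, 2 higher and 0 lower without FHC replicate 4 or without HCT116 replicate 1, 2 or 3, and 8 higher and 1 lower without HCT116 replicate 4. The cancer-testis list passed with normexp (adjusted p = 0.0458), with no filter (adjusted p = 0.00681), with probes detected on all arrays only (adjusted p = 0.0474), without FHC replicate 1 (adjusted p = 0.0454) and without HCT116 replicate 4 (adjusted p = 0.0066). With normexp, the call was lost for HK1, SRSF3, TBP, COX7C, MAGEA2 and XAGE1B. With quantile normalization, with the deposited table or with the percentile over probes detected on all arrays, no call was made for VCP, TBP and SDHC. With spike-in scaling, the call was lost for SLC16A3, HK1, MAGEA2 and XAGE1B. A lower percentile was subtracted on HCT116 replicates 1 to 3, so the rises of MAGEA2 and XAGE1B may come in part from the scaling, which was not tested. With cyclic loess, no call was made for VCP, TBP, SDHC and MAGEA2. With only replicate 4 for HCT116, the call was lost for SLC16A3, TBP, COX7C, MAGEA2 and XAGE1B. Without FHC replicate 1 or without FHC replicate 2, no call was made for XAGE1B.

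The lncRNA comparison asked the same of long noncoding transcripts. The largest rises among named lncRNAs were in HOTAIRM1 (chromosome 7, 27096124 to 27099966), transcribed from the HOXA cluster, at least 117-fold higher in HCT116, in HAR1A, at least 40.9-fold, and in TIAM1-AS1, at least 30.1-fold. PIK3CD-AS2 was -1.16 ± 0.14 in FHC and 5.08 ± 0.39 in HCT116 (log2 fold change 6.24, standard error 0.29, adjusted p = 1.25e-06). The largest falls were in PMCHL1, related in sequence to PMCH, at least 82-fold lower, and in SNAR-G1, CDK6-AS1 and TP53TG1, with log2 fold changes of -6.73, -6.24 and -5.36. PMCH fell too, so its share in the PMCHL1 signal is uncertain. SNAR-G1 was 10.31 ± 0.21 in FHC and 3.58 ± 2.10 in HCT116, with 0.54 on HCT116 replicate 4 and 3.83 to 4.99 on replicates 1 to 3. The CDK6-AS1 probe used was well above background on 3 of 4 HCT116 arrays, and over both its probes CDK6-AS1 was so on all 4. Of 47 measured cancer-associated lncRNAs, 8 rose and 10 fell (adjusted over the list alone, 8 rose and 10 fell), with LINC00460 at 5.04 and UCA1 at -3.69. With HCT116 replicate 4 as the only HCT116 array, 11 rose and 10 fell. Cancer-associated lncRNA counts were 3 higher and 14 lower with spike-in scaling, 15 higher and 6 lower with the percentile over probes detected on all arrays, and 11 higher and 9 lower with cyclic loess. Over all lncRNAs, 13341 passed the limma test, 9370 higher and 3971 lower. The 4 arrays with the lowest 75th percentile were HCT116 replicates 1 to 3 and FHC replicate 3, and setting these against the other 4 called 18830 lncRNAs, more than the split by cell line. The share of calls lower in HCT116 was 29.8%, and was 65% with normexp, 91.3% with spike-in scaling, 10.8% with the percentile taken over probes detected on all arrays and 31% with cyclic loess. It was 58.4% of 7281 calls with HCT116 replicate 4 as the only HCT116 array. Leaving out FHC replicate 1, 2 or 4 gave 7277, 8783 and 7720 calls, leaving out HCT116 replicate 1 or 3 gave 8891 and 8876, and leaving out HCT116 replicate 4 gave 29118. The lncRNA count therefore cannot be read as a difference between the lines alone.

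The circRNA comparison used the circRNA probes and asked which circular transcripts differ between the lines. The largest rises were in circRNAs of PTPRS (hsa_circ_0048725, at least 126-fold higher in HCT116), DBN1 (hsa_circ_0075196, at least 247-fold), FSCN1 (hsa_circ_0004175, at least 89.3-fold) and SCARA3 (hsa_circ_0083771, at least 71.1-fold). The largest falls were in circRNAs of LYZ (hsa_circ_0027510, log2 fold change -10.21), GALC (hsa_circ_0032846, at least 41.7-fold lower), SIVA1 (hsa_circ_0033543, -6.80) and FGG (hsa_circ_0071323, -6.73). hsa_circ_0027510 was well above background on 1 and hsa_circ_0071323 on 1 of 4 HCT116 arrays. The mean of hsa_circ_0027510 was 8.56 in FHC and -1.66 in HCT116, close to LYZ mRNA at 8.92 and -1.90. Binding of linear LYZ by this probe was not tested, so a fall of the circular form is not settled. Of 3 known circRNAs with a probe, circNRIP1 (hsa_circ_0004771) had a log2 fold change of 1.64 (adjusted p = 0.0119), circITCH (hsa_circ_0001141) -1.77 (adjusted p = 0.0156), and circHIPK3 (hsa_circ_0000284) -0.077 (adjusted p = 0.766). With spike-in scaling circNRIP1 was at 0.39 (adjusted p = 0.326), no longer a call, and circHIPK3 was called lower at -1.33 (adjusted p = 0.0437). The circNRIP1 call was also lost with normexp, at 0.89. None of the 3 was called with HCT116 replicate 4 as the only HCT116 array. Over all circRNAs, 15006 passed the limma test, 2396 higher and 12610 lower. With HCT116 replicate 4 as the only HCT116 array, 8228 were called, and without FHC replicate 1 9898. The share of calls lower in HCT116 was 84%, and was 93.4% with normexp, 98.8% with spike-in scaling, 54.5% with the percentile taken over probes detected on all arrays and 80% with cyclic loess.

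CircRNA and host mRNA fold changes were correlated across 33246 circRNAs of 5897 host genes, with Pearson r = 0.544 and Spearman rho = 0.474. CircRNAs are not independent replicates, so this describes these arrays. Among 9502 circRNAs called together with their host, 327 went the opposite way. The median of circRNA minus host log2 fold change was 0.15, with quartiles -0.36 and 0.83, and did not pass an exact two-sided permutation of the 70 labelled splits (p = 0.257, smallest possible 0.0286). Per array, the median circRNA minus host signal was -0.70, -0.52 and -0.53 log2 units on HCT116 replicates 1 to 3, -1.11 on HCT116 replicate 4, and -0.98 to -0.91 on FHC. Without HCT116 replicate 4 the shift was 0.25 (exact permutation p = 0.0286, the smallest these splits can give), and with that array as the only HCT116 array it was -0.14, with no test.

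**Figure D3:**
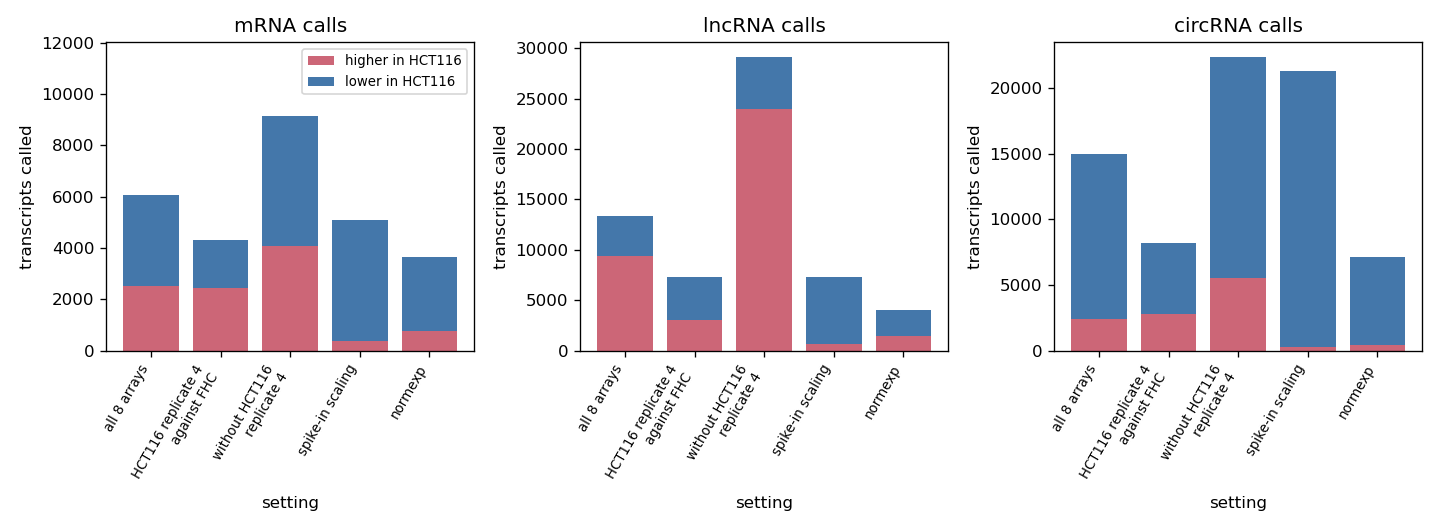
Bars give the number of transcripts called (vertical axis) under 5 settings (horizontal axis), red for higher and blue for lower in HCT116, in a panel for each RNA class. LncRNA calls number 13341 with all 8 arrays and 29118 without HCT116 replicate 4.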

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

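The tests of the dim HCT116 arrays were chosen after the result was seen; the counts of splits and both tests of the circRNA shift were set out before, though each array's median circRNA signal had been seen by then. Of 214 sets of 4 arrays tested for 1 array far from the other 3, 6 stood out. Chance alone picks about 1 in 20 sets, which is more than these 6, so the sets below may be chance picks. HCT116 replicate 4 was the far array for S100A4 (9.35 on HCT116 replicate 4, 11.17 to 11.54 on the others, gap over range 0.832), LAPTM5 (-1.06 on HCT116 replicate 4, -0.01 to 0.21 on the others, gap over range 0.83), THY1 (-0.15 on HCT116 replicate 4, 1.75 to 2.09 on the others, gap over range 0.845) and MAGEA2 (-1.37 on HCT116 replicate 4, -0.17 to -0.0056 on the others, gap over range 0.877). FHC replicate 3 was the far array for hsa_circ_0004175 (-2.70 on FHC replicate 3, -5.12 to -4.72 on the others, gap over range 0.836). The PGK1 3' to 5' ratio was 60.8 on FHC replicate 2 and 59.3 to 59.5 on the other FHC arrays (gap over range 0.856).

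Bright mRNA probes were a median 2.55 log2 units dimmer on HCT116 replicate 3 than on replicate 4, with quartiles of 1.56 and 3.53 over 6113 probes. Less labelled RNA by one factor is argued against, since the interquartile range of the difference was 6.17 times the widest between 2 FHC arrays. Replicate 4 holding mainly FHC RNA, or being a mislabelled FHC array, is argued against by 16 mRNA probes bright in FHC and not well above background on HCT116 replicates 1 to 3: on replicate 4, 14 were not well above background, the closest to FHC lay at -3.82 log2 units from it, and the median of -8.52 is only a bound. RNA degradation stays open: the loss rose with distance from the 3' end at rho = 0.188, the GAPDH ratio lay above FHC on all 4 HCT116 arrays and further above on replicates 1 to 3, and the PGK1 ratio lay above FHC on replicate 1 (63.7) and below it on replicates 2 and 3 (58.5 and 57). A difference in the state of the cultures was not tested and stays open too.

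For the shift of circRNAs against their host mRNAs, the dim arrays are a candidate explanation, since with HCT116 replicate 4 as the only HCT116 array the shift turned to -0.14. Binding of the linear host by circRNA probes cannot be told apart from shared regulation of host and circRNA, as the fold changes correlated at r = 0.544 and the shift itself did not pass its test.

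Of the 35 splits of the 8 arrays into 4 and 4, 1, the split by line itself, gave as many mRNA calls as the split by line. It gave 6073 calls, with 0 in the highest other split. For circRNAs 1 did so too, again the split by line (15006 calls, highest other 0). A mixed split holds any difference between the lines inside its groups, which widens their spread, so few calls there say little about chance. The split by line is also the split by slide, so effects of slide or array are not excluded. For lncRNAs 2 of 35 splits gave as many, the real one included, with 13341 calls for the real split and 18830 for the highest other, so chance cannot be excluded. No slide held both lines, so no value within a slide can be had. That other split puts the 3 dim HCT116 arrays together with FHC replicate 3 and points to a structure of the arrays that is not the cell line. Before scaling, median lncRNA signal was 11.2 to 13.4 intensity units on FHC and 11.5 to 14.2 on HCT116. The percentile subtracted in scaling was 33.8 to 47.4 on the dim arrays. On FHC replicate 3 it was 84.1, the lowest of FHC, and on HCT116 replicate 4 it was 106. The split may thus come from the scaling and not from the samples, which was not tested. For gene lists 5 of 35 splits, the real one included, put as many past the threshold as the 11 of the real split. The highest other split put 14. The other 4 each put 3 FHC arrays with HCT116 replicate 1, against 1 FHC array and HCT116 replicates 2 to 4. They keep part of the difference between the lines, so they are not a reference for chance. The splits thus do not decide whether chance gives as many lists at the preset correlation, and chance is not excluded.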

How the results depend on the processing

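Cyclic loess, the percentile over detected probes and HCT116 replicate 4 alone were chosen after the data were seen, and no cause of the changes below was tested. Of the spots, 56.5%, 48.6% and 53% were well above background on the dim HCT116 replicates 1, 2 and 3, against 50.3% on replicate 4. List values are the list median minus the median of all mRNAs (log2), with camera's adjusted p. Of 98 named transcripts, 67 kept direction and call under every alternative that gave a value. They were picked from these same data for large changes or small p, which favours such stability. With probes detected on all arrays only, 55 were unchanged, 1 lost its call and the others gave no value. With normexp: mRNAs 3637 calls (783 higher), lncRNAs 4070 calls (1423 higher), circRNAs 7115 calls (471 higher), cancer-testis antigens 0.67 (adjusted p = 0.0458), housekeeping -0.75 (adjusted p = 0.0359), known circRNAs 1 calls, COX4I1 0.094. With quantile normalization: fibroblast collagens and matrix 0.77 (adjusted p = 0.0838). With spike-in scaling: lncRNAs 7337 calls (641 higher), epithelial adhesion and keratins -0.93 (adjusted p = 0.0628), fibroblast collagens and matrix 1.1 (adjusted p = 0.0953), p53 targets -1.01 (adjusted p = 0.0809), DNA mismatch repair -1.09 (adjusted p = 0.0628), TIE1 -0.12, JUNB -0.14, CD2 -0.12, BGN -0.12, PAGE2 -0.17. With no filter: cancer-testis antigens 0.65 (adjusted p = 0.00681), housekeeping -1.15 (adjusted p = 0.00719). With probes detected on all arrays only: circRNAs 8996 calls (1831 higher), mesenchymal regulators and cytoskeleton 1.48 (adjusted p = 0.0444), fibroblast collagens and matrix 0.97 (adjusted p = 0.125), secreted cytokines and proteases 1.47 (adjusted p = 0.0444), cancer-testis antigens 1.28 (adjusted p = 0.0474). With the mean of a gene's probes: housekeeping -0.55 (adjusted p = 0.0235). With the deposited table: fibroblast collagens and matrix 0.77 (adjusted p = 0.084). With cyclic loess: fibroblast collagens and matrix 0.42 (adjusted p = 0.279), endothelial 0.27 (adjusted p = 0.0651), leukocyte 0.80 (adjusted p = 0.0651). At an absolute log2 fold change of at least 2: mRNAs 1982 calls (777 higher), lncRNAs 2934 calls (1576 higher), circRNAs 4248 calls (511 higher). With HCT116 replicate 4 alone against FHC: lncRNAs 7281 calls (3032 higher), circRNAs 8228 calls (2794 higher), circRNA and host mRNA 0.74, circRNA shift relative to host mRNA -0.14, fibroblast collagens and matrix 0.0074 (adjusted p = 0.84), endothelial 1.40 (adjusted p = 0.0745), leukocyte 0.34 (adjusted p = 0.714), MAPK output 1.21 (adjusted p = 7.76e-04), p53 targets -0.92 (adjusted p = 0.0629), DNA mismatch repair -0.30 (adjusted p = 0.238), circRNA biogenesis and turnover factors -0.23 (adjusted p = 0.419), known circRNAs 0 calls. With an estimated correlation no list passed: epithelial adhesion and keratins -0.93 (adjusted p = 0.571), fibroblast collagens and matrix 1.1 (adjusted p = 0.37), endothelial 1.38 (adjusted p = 0.214), leukocyte 1.42 (adjusted p = 0.487), intestinal epithelial identity 1.79 (adjusted p = 0.214), cell cycle -1.02 (adjusted p = 0.477), p53 targets -1.01 (adjusted p = 0.477), DNA mismatch repair -1.09 (adjusted p = 0.477), interferon-stimulated genes -1.15 (adjusted p = 0.37), HOX genes 1.70 (adjusted p = 0.214), circRNA biogenesis and turnover factors -1.05 (adjusted p = 0.58). Leaving out 1 array at a time gave ranges of 7277 to 29118 (lncRNA calls), 9898 to 22351 (circRNA calls), 1.00 to 1.80 (cancer-testis antigens), 4436 to 9152 (mRNA calls), 0.10 to 0.25 (circRNA shift relative to host mRNA), -1.39 to -0.60 (Wnt/beta-catenin targets and feedback), -0.64 to 0.036 (MAPK output), -0.29 to -0.11 (TGF-beta targets), 0.13 to 0.44 (HLA class I and antigen processing), -0.19 to 0.077 (glycolysis), -0.054 to 0.17 (oxidative phosphorylation), with the highest counts of calls without HCT116 replicate 4. Whether the replicate numbers pair samples is not settled. Same-numbered deviations correlated from -0.253 to 0.417, with 1 of 4 pairs over 0.1. Differently numbered arrays correlated up to 0.468, for FHC replicate 1 with HCT116 replicate 4. With the replicate block, calls numbered 6560 mRNAs, 14437 lncRNAs and 15509 circRNAs, and it changed neither which lists passed nor the call of a named transcript, while counts within lists moved (cancer-associated lncRNAs 9 higher and 13 lower). 3 of the 8 arrays correlated best with their own number. Slide as a block was not run.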

Other observations

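The correlations given here were chosen after the result was seen. Over bright mRNA probes, the loss on HCT116 replicate 3 against replicate 4 followed transcript length at rho = 0.399 and probe GC content at rho = -0.306, across probes that are not independent.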
